A study of Drosophila melanogaster with 2 samples.

How the data were processed

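Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster carrying a GFP-tagged copy of Spineless, per the labels. Spineless (ss) is a basic helix-loop-helix PAS transcription factor, the fly homolog of the vertebrate aryl hydrocarbon receptor (AHR), and it binds DNA together with Tango (tgo), the homolog of ARNT. The labels describe whole animals of both sexes at the prepupal stage, aged 24 hours, chromatin fragmented by sonication, and an antibody against GFP. The antibody tag in the labels reads ss instead, and the antibody against GFP named in the description was taken as the one used. There was 1 group with 2 biological replicates, so no condition was compared with another. The labels name the tagged isoform in 2 ways, as ss-RA in one place and as ss-RB with the GFP at the C-terminus in another, and which is right was not settled here. The labels call the flies transgenic. Whether the tag sits on an added copy of the locus or on the resident gene is otherwise not given in the sources used here.

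The data used here were deposited lists of peaks. Per the deposited README notes, each replicate has a list of candidate peaks made from its own alignment and a control file. A pooled list was made from the alignments of both replicates, and an optimal set was selected from these lists by irreproducible discovery rate (IDR) analysis. Every list was deposited on the dm6 and the dm3 genome builds. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each peak has a start, an end, a summit, a signal value and a −log10 q-value, as the authors' deposited lists give them. The signal is on the peak caller's own scale, per the file format, so it was used to rank peaks within a list and was compared between replicates only across matched peaks. The deposited −log10 q-value saturates (86.6% of the dm6 optimal set stood at its highest value, 4.18) and was not used for ranking. Read depth is unknown, since no list gives read counts. No interval given here includes sequencing error. Intervals on shares are exact (Clopper-Pearson) 95% intervals over peaks or genes, and those on odds ratios are 95% intervals on the log scale.

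Analyses used the dm6 lists and the 6 main arms 2L, 2R, 3L, 3R, 4 and X. Annotation came from Ensembl release 115 (FlyBase annotation 6.54), with 13945 protein-coding genes and 19607 annotated transcription start sites (TSSs), and sequence came from the Release 6 genome. No coordinates were converted between builds, and dm3 was compared by counts and signal alone. Coordinates are 1-based and on dm6. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

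Replicates were compared over the 8637 strongest candidates of each, the size of the optimal set. A summit counted as shared when a summit of the other replicate lay within 100 bp, and the chance share came from 100 random shifts along the same arm. Summits were assigned to promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, intron or intergenic sequence, in that order. The background was the 18632 pooled candidates that overlap no optimal peak, compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 6 classes. Motifs were counted on either strand in windows of 201 bp centred on the summit, against as many background candidates matched on GC content in bins of 2 percentage points. The 9 motifs were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, and GCGTG was ranked by odds ratio among all pairs of complementary pentamers. The relation of GCGTG to signal was a Spearman correlation across peaks with a two-sided permutation test (100000 permutations). A protein-coding gene was called bound when an optimal summit lay within 1 kb of one of its TSSs. A peak near several genes counted for each of them. Each of 16 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. The X chromosome was tested with a two-sided exact binomial test. Peaks and genes are not replicates, so every p-value describes these lists rather than variation between animals. Most results were also computed from each replicate's own list.

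The lists, motifs, tests and most alternatives were fixed before the data were examined. The lists were appendage patterning, Hox genes, signalling pathways of imaginal discs, ecdysone response, Notch and sensory organ, dendrite morphogenesis, retinal transcription factors, rhodopsins and phototransduction, bHLH-PAS factors and partners, circadian clock, cytochrome P450 and glutathione transferase, muscle structure, ribosomal proteins, cuticle proteins, olfactory and gustatory receptors, and seminal fluid proteins. Of the names in them, 3 matched no annotated gene (let-7-C, inaF and XAP2). Some genes belong to several lists, such as ss in the dendrite, retinal and bHLH-PAS lists, so the lists are not independent. The rule for named genes took ss and tgo, the gene with the TSS nearest to each of the 15 strongest optimal summits, and from each list up to 4 bound members with the highest signal and the first 2 unbound members in list order. Any other gene named is said to have been chosen after its values were seen. Alternatives varied the matching distance, the number of peaks compared, the promoter and motif windows, the backgrounds, the 4318 optimal peaks with the highest signal, each replicate's own list, the gene assignment and random lists matched on gene length. Random lists matched on the number of TSSs and on length (10000 per list) were added after the data were seen. Their p-values are two-sided permutation p-values over the drawn lists, of which the smallest possible is 2.00e-04, with Benjamini-Hochberg adjustment over the 16 lists.

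The statistics were tested on simulated data. A planted replicate overlap of 60.3% over 8637 peaks was recovered as 60.5%. A planted motif odds ratio of 2.50 over 2453 windows was recovered as 2.55, and with nothing planted the estimate was 1.12. Of 96 simulated lists raised from 25% to 60% bound, 99.0% were called, and of 96 unchanged lists 0% were. The simulated lists were drawn at random, with binding unrelated to TSS number or gene length. They therefore do not show how often such differences alone lead to a call.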

Results

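The binding sites of GFP-tagged Spineless in whole prepupae were recorded in 2 biological replicates of 1 group. Each replicate's list held exactly 30000 candidate peaks, as did the pooled list, on both builds. The pooled list is labelled as peaks and background for the IDR analysis. The number is therefore the size of a list and not a count of binding sites. The optimal set held 8637 peaks, which merged into 7550 separate regions because some peaks overlap. The median peak was 464 bp wide (range 116 to 2146 bp). Signal, on the caller's scale, ran from 150.1 to 5334, with a median of 257. The optimal set was exactly the 8637 pooled candidates with the highest signal. On dm3 the corresponding set held 8578 peaks, with a median signal of 253.

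The strongest peaks in these animals lay at genes of varied function, several of them within promoters. The highest signal, 5334, belonged to a peak at 2R 22569676 to 22570638 in an intron of dnr1. The nearest TSS there, 7683 bp away, is that of CG11362. The next was at the promoter of yip2 (2L 9915054 to 9915823, signal 4329), followed by Cat, which encodes catalase (3L 18822523 to 18823224, signal 3902, summit 312 bp from the TSS). Promoter peaks at Ugalt, a UDP-galactose transporter (signal 3665), larp, which encodes an RNA-binding protein (signal 3647), and puc, the phosphatase that restrains JNK signalling (signal 3168), were among the first 8. The transcription factor gene cbt was the nearest gene to 2 of the first 15 peaks, with signals of 2872 and 2737, the stronger of them in an intron of ush. The other nearest genes were dob (the summit lies in the 3' UTR of Lsd-2), CG8788, CG11050, CG32772, CG43389, CG4004 and CG18549. The 3 strongest peaks ranked 1, 3 and 2 in replicate 1 and 1, 2 and 8 in replicate 2.

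How far the replicates recovered the same sites was the one comparison between samples that the design allows. Of the 8637 strongest summits of replicate 1, 6288 (72.8%, 95% interval 71.9 to 73.7%) lay within 100 bp of one of the 8637 strongest of replicate 2. Randomly shifted summits gave a mean of 1.31% and at most 1.60% in 100 draws. Across the 8035 optimal peaks with a candidate in both replicates, signal correlated with a Spearman coefficient of 0.753 and a Pearson coefficient of 0.916, across peaks, which are not independent replicates. The median ratio of replicate 1 over replicate 2 was 1.15. The SD of the log2 ratio was 0.54, and 93.3% of the peaks were within 2-fold of that median ratio. In 5 bins of equal size, from strongest to weakest, 97.7%, 95.6%, 92.8%, 90.7% and 88.3% of optimal peaks had a match among all candidates of both replicates. No chance share was computed for these matches. The optimal set was itself drawn from both replicates by IDR analysis, which favours peaks found in both. These shares and the correlations above are therefore no independent measure of agreement. Against only the 8637 strongest of each, the weakest bin fell to 18.8%, but its peaks sit at the same rank cut, which by itself lowers that share. Under the same selection by IDR, 173 optimal peaks (2.00%) matched the 8637 strongest of neither replicate.

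The distribution of the peaks over gene features was compared with that of the weaker candidates. Promoters held 2676 of 8637 optimal summits (31.0%), against 14.0% of the other candidates and 11.6% of random positions. Introns held the largest share, 44.0% against 50.6% of the other candidates, and intergenic sequence held 22.5% against 30.7%. Coding exons (0.741% against 2.10%) and 3' UTRs (0.799% against 1.65%) were lower in the optimal set too. Of random positions, 39.4% lay in introns, 29.8% in intergenic sequence, 13.9% in coding exons and 4.47% in 3' UTRs. Against these the optimal set was higher in introns and lower in the other 3 classes. For promoters the odds ratio was 2.76 (2.59 to 2.93, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 2.09e-225), and replicates 1 and 2 alone had promoter shares of 31.7% and 30.6%. The 5' UTR share did not pass the test (1.02% against 0.939%, exact adjusted p = 0.549). The promoter share varied little with signal, from 29.2% to 34.6% over the 5 bins.

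**Figure D1:**
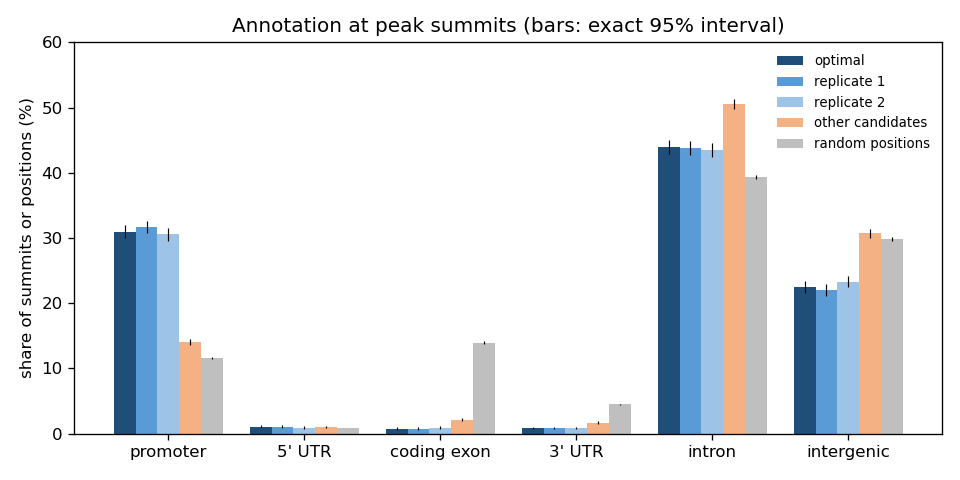
Share of summits (vertical axis, percent) in each class of annotation for the optimal set, the 8637 strongest candidates of each replicate, the other candidates and random positions, with exact 95% intervals as error bars. Promoters hold 31.0% of the optimal summits and 14.0% of the other candidates.

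The peaks were next searched for GCGTG, the core of the xenobiotic response element that AHR with ARNT and Spineless with Tango are known to bind. GCGTG was present within 100 bp of 38.0% of optimal summits (3280 of 8624) and 29.1% of GC-matched candidates, an odds ratio of 1.50 (1.41 to 1.60, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 5.33e-35 over 9 motifs). The extended element TNGCGTG had an odds ratio of 1.82 (14.9% against 8.79%, exact adjusted p = 5.24e-35). GAGAG, the core read by GAGA factor, was also higher, with an odds ratio of 1.49 (34.0% against 25.7%, exact adjusted p = 5.55e-32). ACGTG, which Tango reads with its other partners Sim, Trh and Sima, was not higher (16.4% against 17.2%, odds ratio 0.947, exact adjusted p = 0.278). The palindromic E-box CACGTG (odds ratio 0.899, exact adjusted p = 0.388), the Zelda element CAGGTAG (0.917, exact adjusted p = 0.682) and the DREF element TATCGATA (1.09, exact adjusted p = 0.754) did not pass the test either.

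Among all pairs of complementary pentamers GCGTG ranked 1 by odds ratio, ahead of GAGAG (1.49), ACGCG (1.48) and CGCGA (1.45). In replicate 1 alone it ranked 2, behind GAGAG (1.49 and 1.50), and in replicate 2 alone it ranked 1 (1.53). GCGTG was concentrated at the summit: its density within 50 bp was 1.79 times (1.69 to 1.91) that at 200 to 250 bp, against 1.26 times (1.18 to 1.34) for the reversed pentamer GTGCG, 0.991 times for ACGTG and 1.18 times for GAGAG. At the summits of the other candidates GCGTG was concentrated too, at 1.53 times (1.46 to 1.60). The reversed pentamers were also higher in the optimal set. GTGCG, with the base composition of GCGTG, had an odds ratio of 1.32 (1.24 to 1.41, exact adjusted p = 5.59e-17). GTGCA, with the base composition of ACGTG, had 1.14 (exact adjusted p = 7.99e-05), although ACGTG itself was not higher. The intervals of GCGTG and GTGCG touched, with a lower bound of 1.405 and an upper bound of 1.406.

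**Figure D2:**
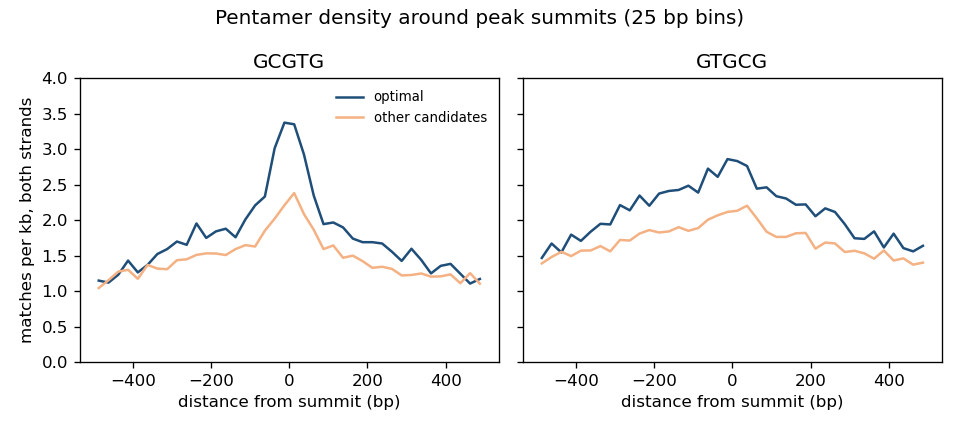
Matches per kb (vertical axis) of GCGTG and of the reversed pentamer GTGCG by distance from the summit in bp (horizontal axis), for optimal peaks and other candidates. GCGTG rises to 3.38 matches per kb in optimal peaks beside the summit.

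From the strongest to the weakest of 5 bins, 35%, 39.7%, 40.6%, 38.4% and 36.2% of optimal summits carried the core. The share did not pass a test for a steady rise or fall with signal (Spearman correlation −0.0041, two-sided permutation p = 0.702, across peaks). The interval of the strongest bin (32.76 to 37.31%) nevertheless lay below those of the next 2 bins (37.35 to 42.02% and 38.2 to 42.9%), a difference between bins that was seen afterwards and not tested. Without replicate 1 the intervals overlapped (34.7 to 39.3% against 37.5 to 42.2%). Without replicate 2 that of the strongest bin (32.19 to 36.73%) overlapped that of the second (36.66 to 41.32%) but not that of the third (37.15 to 41.82%). GAGAG was also lower in the strongest bin (30.5% against 36.0% and 37.0%). Among promoter summits alone, the correlation was −0.055 (permutation p = 0.00475), with 30.6% in the strongest bin and 38.7% to 42.8% in the others. Among all other summits it was 0.018 (permutation p = 0.158).

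In all, 2884 of 13945 protein-coding genes (20.7%) had an optimal summit within 1 kb of a TSS, and replicates 1 and 2 alone gave 2971 and 2859. Of these genes, 2443 were found in the optimal set and in both replicates. In the appendage patterning list, 25 of 40 genes were bound (odds ratio 6.44, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 3.42e-08 over 16 lists), with 30 in replicate 1 and 22 in replicate 2. Without replicate 2 the odds ratio was 11.2, and without replicate 1 it was 4.77. With the 4318 strongest optimal peaks it was 2.72 (11 of 40, exact adjusted p = 0.0115), and over gene bodies it was 15.9. The bound genes included ap, the selector of dorsal wing identity (signal 964), the leg segmentation gene bowl (signal 727), ct (signal 533) and bab2 (rank 1371). The promoters of tgo and hth, whose product acts with Exd in the antenna, were not bound. Of the signalling pathways of imaginal discs, 27 of 37 genes were bound (odds ratio 10.4, exact adjusted p = 6.18e-11), among them aos, an inhibitor of the EGF receptor (signal 910), the Dpp receptor gene tkv (signal 865), the EGF receptor ligand gene spi (signal 675) and pnt (signal 516). Wnt10 and arm were not bound, and the summit assigned to aos lies in an intron of CG33158. With the 4318 strongest peaks the odds ratio of this list was 4.91 (15 of 37). Notch and sensory organ genes were bound in 26 of 38 cases (odds ratio 8.38, exact adjusted p = 1.13e-09), including elav (signal 1183), E(spl)m7-HLH (signal 886), numb (signal 874) and fng (signal 743), but not Su(H) or H. Random lists matched on TSS number and length, added after the data were seen, averaged 39.5%, 40.2% and 28.3% bound for the appendage, signalling and Notch lists. The ratios to these means were 1.58, 1.81 and 2.42 (adjusted permutation p = 0.00533, 8.00e-04 and 8.00e-04).

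Among the bHLH-PAS factors and partners, 11 of 16 were bound (odds ratio 8.47, exact adjusted p = 7.97e-05). These were led by Hsp83, the Hsp90 chaperone (signal 1161), and included ss itself (signal 491), the coactivator gene tai (signal 476) and dysf (signal 470), but not tgo or Clk. The list passed against random lists matched on TSS number and length, added after the data were seen (ratio 1.77, adjusted permutation p = 0.0334). The tagged gene ss counts as bound in it, as in the dendrite and retinal lists, and no value without ss is given here. Counting summits over whole gene bodies, the bHLH-PAS list did not pass against random lists matched on length (ratio 1.47, adjusted permutation p = 0.165). Ribosomal protein genes, which are active in nearly every cell, were bound in 66 of 92 cases (odds ratio 9.94, exact adjusted p = 1.02e-24). Examples were RpS4 (signal 627), RpL30 (signal 603) and RpS10b (signal 550). The peak assigned to RpS19b (signal 816) lay 881 bp from its TSS and inside CG5854, and RpL10Aa and RpL11 were not bound.

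Ecdysone response genes were bound in 20 of 36 cases (odds ratio 4.82, exact adjusted p = 1.18e-05), with peaks at Eip93F (signal 1177), E23 (signal 969), Ldh (signal 904) and Eip75B (signal 881). The promoters of Hr3 and Hr78 were not bound. Dendrite morphogenesis genes were bound in 15 of 29 cases (odds ratio 4.13, exact adjusted p = 3.31e-04), with lola (signal 997), ct, tutl (signal 533) and ss at the top and kn and seq unbound. Retinal transcription factors were bound in 16 of 28 cases (odds ratio 5.14, exact adjusted p = 5.76e-05). They were led by ss itself (signal 491) and included klu (signal 431), mirr (signal 381) and oc (signal 353), but not toy or gl. With the 4318 strongest optimal peaks the retinal list did not pass (odds ratio 1.95, exact adjusted p = 0.194), and without replicate 1 the odds ratio was 2.92 (12 of 28). Circadian clock genes were bound in 10 of 19 cases (odds ratio 4.27, exact adjusted p = 0.00298), including sgg (signal 1187), cry (signal 627) and vri (signal 403), but not per or tim. These 4 lists did not stand apart from random lists matched on the number of TSSs and on gene length, a comparison added after the data were seen. The ratios of the observed to the mean random share were 1.35 (adjusted permutation p = 0.144), 1.34 (adjusted permutation p = 0.248), 1.40 (adjusted permutation p = 0.153) and 1.20 (adjusted permutation p = 0.664) in the order given. In the comparison planned beforehand, over gene bodies and matched on length, the ecdysone list passed (24 of 36, ratio 1.49, adjusted permutation p = 0.0149) and the other 3 did not.

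Bound promoters were fewer than among other genes in 2 lists. Of the olfactory and gustatory receptors, 2 of 179 were bound, Or88a (signal 215) and Gr97a (signal 157), an odds ratio of 0.0427 (exact adjusted p = 1.24e-14). Their summits lay 956 and 660 bp from the receptors' TSSs, the one near Gr97a inside CG5521, and within 500 bp 0 of 179 were bound. Gr10a and Gr10b were not bound at either distance. Without replicate 1 the odds ratio was 0.0874 (4 of 179). Cuticle proteins were bound in 8 of 119 cases (odds ratio 0.274, exact adjusted p = 7.01e-05), led by Cpr72Eb (signal 681). One peak (signal 315) counted for both Lcp65Ad, 24 bp from its TSS, and Cpr65Aw, 958 bp from its TSS, and Cpr97Eb had a signal of 234. Acp65Aa and Ccp84Aa were not bound. Without replicate 2 the odds ratio was 0.161 (5 of 119). The cuticle call was lost against random lists matched on TSS number and length (ratio 0.604, adjusted permutation p = 0.214).

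The remaining 5 lists did not pass the main test. Cytochrome P450 and glutathione transferase genes, which include targets of AHR in vertebrates, were bound in 16 of 118 cases (odds ratio 0.599, exact adjusted p = 0.0822), with peaks at GstT4 (signal 1131), GstE13 (signal 915), GstT1 (signal 646) and, inside an intron of Svil, near Cyp4d20 (signal 1023). Cyp12a4 and Cyp12a5 were not bound. This list did pass, as lower, within 2 kb (0.550), over gene bodies (0.531) and without replicate 2 (0.536). It did not pass against random lists matched on TSS number and length (ratio 0.962, adjusted permutation p = 1) or over gene bodies matched on length (ratio 0.832, adjusted permutation p = 0.527). Rhodopsins and phototransduction genes were bound in 9 of 30 cases (odds ratio 1.65, exact adjusted p = 0.292). Rh5 (signal 555), rdgC (signal 382) and norpA (signal 351) were among them, and ninaE and Rh2 were not. Of the Hox genes, Dfd (signal 188) and Scr (signal 174) were bound and lab and pb were not (2 of 8, odds ratio 1.28, exact adjusted p = 0.673). When summits anywhere in the gene body counted, the Hox list passed (odds ratio 19.5, exact adjusted p = 8.06e-04), though not against random lists matched on gene length (7 of 8 genes, adjusted permutation p = 0.373). Without replicate 1 the Hox odds ratio was 2.33 (3 of 8). Muscle structure genes were bound in 5 of 31 cases (odds ratio 0.737, exact adjusted p = 0.673), including Zasp52 (signal 656), Msp300 (signal 570), mys (signal 352) and Tm1 (signal 304), but not Mhc or Act57B. The summit assigned to Zasp52 lies in an intron of tun. Against random lists matched on TSS number and length, the muscle list was lower (ratio 0.373, adjusted permutation p = 0.00128), but over gene bodies and matched on length it did not pass (ratio 0.672, adjusted permutation p = 0.176). Seminal fluid proteins were bound in 4 of 46 cases (odds ratio 0.364, exact adjusted p = 0.0593). The 4 were Acp63F (signal 614), Sfp26Ad (signal 425), Acp32CD (signal 219) and Acp98AB (signal 176), and Acp24A4 and Acp1, whose name denotes an adult cuticle protein, were not bound. The peaks of Acp63F and Acp32CD lie in introns of Scsalpha1 and Samuel, and that of Sfp26Ad lies in Gpdh1. This list passed, as lower, without replicate 1 (0.270), without replicate 2 (0.257), within 500 bp (0.109) and over gene bodies (0.416). Against matched random lists it was not lower, with ratios of 1.02 on TSS number and length (adjusted permutation p = 1) and 1.22 over gene bodies (adjusted permutation p = 0.789).

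**Figure D3:**
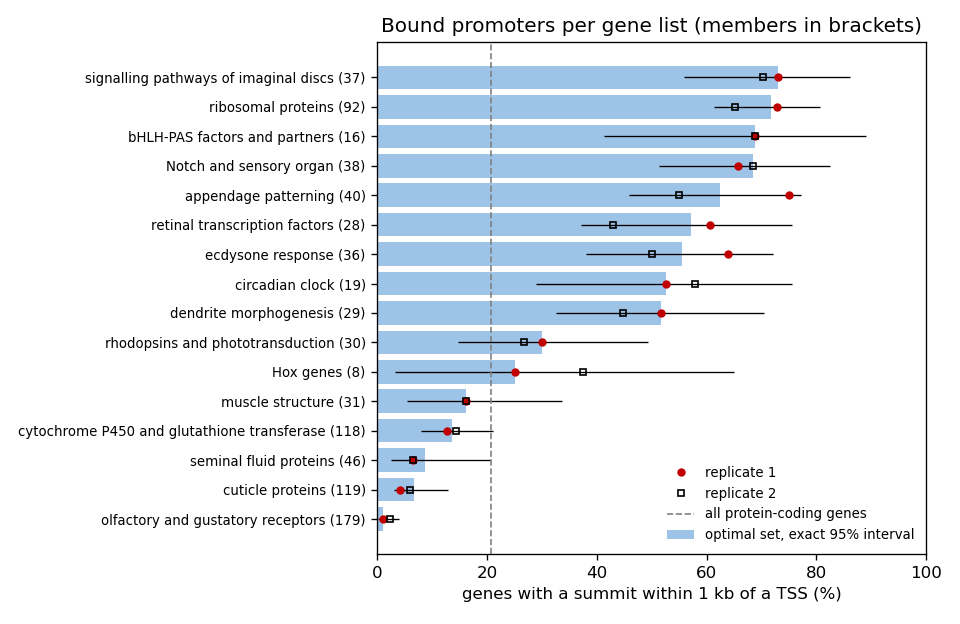
Share of genes with an optimal summit within 1 kb of a TSS (horizontal axis, percent) in each of the 16 lists, with exact 95% intervals, and the share from each replicate's 8637 strongest candidates as points. The dashed line marks all protein-coding genes, 20.7%.

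The tagged gene itself was among the bound genes. ss lies on 3R from 16374434 to 16403690, on the minus strand, and 12 optimal summits lay in it or within 10 kb. The strongest of them, at 3R 16394549 to 16394964 in an intron, had a signal of 1079 and ranked 248 of 8637 (430 in replicate 1 and 137 in replicate 2). The promoter peak, at 3R 16403232 to 16403843, had its stronger summit 270 bp from the TSS, with a signal of 491 and a rank of 1486 (1370 in replicate 1 and 2033 in replicate 2). A stronger peak, named after its value was seen, stood outside the 10 kb, in intergenic sequence at 3R 16416244 to 16417018. Its summit was 13018 bp upstream of the TSS, its signal was 2435, and it ranked 19 (26 in replicate 1 and 12 in replicate 2). At tgo no promoter peak was called.

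**Figure D4:**
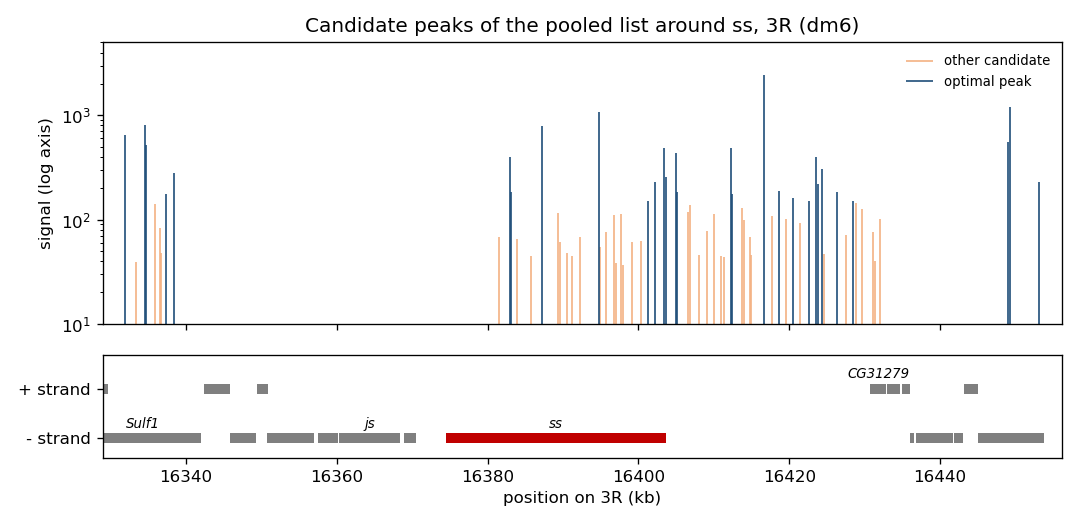
Signal of the pooled candidates (vertical log axis) along 3R in kb (horizontal axis), with optimal peaks and other candidates in separate colours and protein-coding genes below. From 16381435 to 16431990 there are 58 candidates, and none from 16338451 to 16381434, limits set by the candidates themselves. The empty stretch takes in the 3' end of ss.

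Peaks per Mb were similar on the large arms, 62.8 on 2L, 67.3 on 2R, 70.0 on 3L, 59.8 on 3R and 65.8 on X, while the small chromosome 4 had 18.5 per Mb (25 peaks). The X held 1548 optimal peaks, 17.9% of the set against 20.3% of the other candidates (ratio 0.884, two-sided exact binomial test, p = 3.75e-08, Benjamini-Hochberg adjusted p = 1.13e-07 over 6 arms). Against its share of the sequence, 17.6%, the X was not lower (ratio 1.02, exact binomial p = 0.412). Chromosome arms 2R (19.7% against 17.2%, exact adjusted p = 1.07e-08) and 3L (22.8% against 21.7%, exact adjusted p = 0.0327) held more of the optimal set than of the other candidates. The binomial test takes the shares among the other candidates as exact, so these p-values are too small. This matters most for 3L, whose value lies near the threshold.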

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

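Random lists matched on TSS number and gene length were added after the data were seen, and every other alternative was fixed beforehand. Of 153 alternative values with a test, 119 kept their direction and their side of the threshold, including every alternative for promoter location and for GCGTG. Another 13 changed direction, 11 no longer passed and 10 newly passed. Of 17 values with no test, 9 were classed as moved and 8 as the same, a looser class than an unchanged value. Against 8637 optimal peaks, dm3 had 8578, and 6278 were matched by the strongest candidates of both replicates. Against 11 lists in the main test, between 10 (stricter set) and 14 (gene bodies) passed Fisher's test in the alternatives. Causes of the differences below were not tested. The replicate overlap was 83.1% when regions had to overlap by 1 bp, 70.2% with a reciprocal overlap of 50%, 58.3% within 50 bp and 82.2% within 250 bp, 75.9% over 4318 peaks and 67.9% over 17274. The stricter optimal set, by signal, held 4318 peaks. The correlation of signal with GCGTG was 0.0013 with 50 bp each side, 0.0106 with 200 bp, −0.055 over promoter summits and 0.018 over the others, and leaving out one replicate gave −0.0051 to 0.0032.

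Of 16 lists, 11 passed the main test and 14 passed Fisher's test over gene bodies. By permutation against random lists, a different test, 6 passed over gene bodies matched on length and 7 within 1 kb of a TSS matched on TSS number and length. Over gene bodies the ratios of observed to mean random share were 1.34 for dendrite, 1.39 for retinal, 1.47 for bHLH-PAS, 1.15 for circadian and 0.636 for cuticle genes, none past the threshold, with 0.918 for rhodopsins and 1.22 for seminal fluid proteins. Matched on TSS number they were 1.35 for ecdysone, 1.34 for dendrite, 1.40 for retinal, 1.20 for circadian, 0.604 for cuticle, 0.481 for Hox and 1.02 for seminal fluid genes, with 0.373 for muscle, past the threshold. Odds ratios moved past the threshold for seminal fluid proteins within 500 bp (0.109) and over gene bodies (0.416), for cytochrome P450 and glutathione transferase within 2 kb (0.550) and over gene bodies (0.531), and for Hox genes over gene bodies (19.5). For muscle genes they were 1.00 within 2 kb, 1.14 over gene bodies and 1.06 with the stricter set, where Hox genes had 0.420 and retinal genes 1.95, no longer past the threshold. Leaving out one replicate gave 0.257 to 0.270 for seminal fluid proteins, past the threshold without either, and 0.536 to 0.651 for cytochrome P450 and glutathione transferase, past it only without replicate 2. Against arm length the X ratio was 1.02. Read depth is unknown, so what it limits could not be assessed. No paired analysis was possible because there was 1 group.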

Other observations

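The genes named in the next 2 paragraphs were chosen after their values were seen. The comparison of promoter peaks by signal, the ratio of the GCGTG and GTGCG odds ratios, the random lists matched on TSS number and the comparison of ss with other appendage genes were likewise chosen only after the results they follow up. The genes with the most optimal summits in the gene body or within 1 kb of it were mostly long. The scribbler gene sbb had 44 (41 in replicate 1 and 44 in replicate 2), jing had 39, Tet had 34, kirre had 34 and shn, a cofactor of Dpp signalling, had 28. The ecdysone genes Eip75B and EcR had 25 and 21, and the cell cycle regulator E2f1 had 22 over a gene of 40.6 kb. The antennal gene hth, with no bound promoter, had 20. Per 10 kb of gene and flanks, sbb had 5.43, E2f1 5.17, shn 4.64, Tet 3.58, jing 3.20 and kirre 0.858.

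At bound promoters, GCGTG was found at 13 of 25 peaks of the appendage patterning list (52.0%, exact 95% interval 31.3 to 72.2%), 14 of 27 of the signalling list and 21 of 66 of the ribosomal protein list (31.8%, 20.9 to 44.4%), against 39.3% of the 2313 peaks counted over all bound genes. Not every summit was counted, since 3396 optimal summits lay within 1 kb of a TSS. In these 3 lists the peaks counted equal the bound genes in number. The intervals of the appendage and ribosomal lists overlap and the differences were not tested. The strongest of the 5 bins of promoter peaks, where GCGTG was less frequent, had a GC content of 39.1% against 44.8% in the others, and the reversed pentamer GTGCG fell with it too (37.5% in the strongest bin and 41.9% to 47.5% in the others, Spearman correlation −0.053, two-sided permutation p = 0.00625, across peaks). Against promoter candidates of matched GC content, the odds ratio of GCGTG was 1.38 in the strongest bin (1.05 to 1.81) and 1.38 in the others (1.21 to 1.56). That of GTGCG was 1.42 in the strongest bin and 1.21 in the others, so in the strongest bin the core did not exceed its reversed control.

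GCGTG was more frequent at optimal summits than at candidates matched on GC content. Promoter sequence in general does not account for it, since away from promoters the odds ratio was 1.51 (1.40 to 1.64). For GC content, the criterion set beforehand, separate intervals for GCGTG and the reversed pentamer GTGCG (odds ratio 1.32), was missed narrowly at bounds of 1.405 and 1.406. The intervals were apart in 7 of 8 alternatives, the exception being windows of 200 bp each side, and the ratio of the odds ratios, a test added after the miss, was 1.14 (1.05 to 1.22 over 1000 bootstraps). Sequence-specific binding may explain the concentration at the summit, where density was 1.79 times that 200 to 250 bp away (1.26 times for GTGCG), but base composition beyond GC content stays open for part of the enrichment, and binding of other factors to the same core was not tested.

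The appendage patterning list had more bound promoters than its TSS number and gene length would give: its share lay at percentile 99.95 of matched random lists. It did not stand out among the raised lists, however. Its ratio to the mean random share was 1.58, against 1.81 for signalling, 2.42 for Notch, 1.77 for bHLH-PAS and 3.73 for ribosomal protein genes. Accessible promoters in general remain a possible explanation, because 71.7% of ribosomal protein genes (61.4 to 80.6%), which have no special role in appendages, were bound as well. A regulatory role of Spineless at these genes may hold too, but no chromatin accessibility or expression data were used here, so it was not tested.

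Candidates of any strength were dense at the ss locus, 35 in the gene and 10 kb around it, at percentile 96.95 of random windows of the same length. This passed the level of 95% set beforehand for extra copies of the locus, which could raise reads there if the tag came with an added copy. The labels call the flies transgenic, but the sources used here do not otherwise settle that point. The candidates below the optimal set were at percentile 94.9, just short of that level. None of the candidates lay in the 3' 7.0 kb of ss, a stretch whose end is set by the first candidate. The stretch that an added copy would cover is not given either. Dense regulatory sequence could give the same picture. Of the 39 other appendage genes, 2, hth (40) and sob (38), had as many candidates in a window of that length. The median was 20, and 2 genes are too few to decide. None had as many optimal summits as ss (12, against 8 at hth, 9 at sob and at most 11, at klu). These counts are of summits and not of separate regions. At ss, 2 of the 12 share the interval 16403232 to 16403843 and others lie in overlapping peaks, so the lead of ss over klu may reflect split peaks. Binding of Spineless at its own gene stays open as well and was not tested, so no explanation of these peaks is favoured.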
